A study of Mus musculus with 6 samples.

How the data were processed

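Labelled RNA from 6 pooled islet samples, 3 control and 3 mutant, was measured on single-colour Agilent mouse arrays with 150 ng of RNA labelled with Cy3 per sample. The authors' scanner files come from Agilent Feature Extraction 10.7.3.1 and hold, per the file headers, spot intensities that the software corrected for background and for trends within each array, with no scaling between arrays. The same deposited files give flags (other values) for saturation, outlying pixels and signal well above background. A further deposited table holds linear intensities that the authors had equalized between arrays by a method the labels do not state. Set against the scanner files, its values followed the median spot signal at rank correlations of 0.999 or more with no background taken off, and its column medians were 270.2, 266.95 and 268.3 in controls A to C and 272.8, 274.5 and 274.55 in mutants A to C. That table served as an alternative. The labels name no statistical method.

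The background-corrected spot intensity was averaged over the spots of a probe on the log2 scale, and the 75th percentile of each array was subtracted. Of 39429 probes, 28361 were tested because the software had called them well above background on every array of at least 1 group. Each gene name was represented by its tested probe with the highest mean signal, which gave 22775 of 31829 gene names. Probe coordinates are those of the files (mm9). Symbols were updated by matching the accessions of the files to a table of mouse genes on GRCm38, which was used for symbols alone. Accessions matched for 15528 representative probes, 1970 of these had another symbol in the files, and 1551 of the unmatched names were symbols in that table. Signal over background took the place of depth, and the number of arrays limits the precision.

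Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes, two-sided), with version 1.17.8 of the data.table package for reading. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 differences are mutant minus control. Folds compare geometric means, and a gene that was not well above background on any array of a group is given a bound, its fold against the lowest signal well above background on each of those arrays (or its own signal where higher). The slide was read from the array barcodes, each slide held both groups, and values are given with slide as a fixed block and within each slide. The letters A to C occur in both groups, and no label says that they mark shared litters. Deviations from the group mean correlated across genes at -0.23, -0.19 and -0.03 between samples of the same letter. Such samples always lay on different slides, and the other pairs on different slides also correlated negatively (-0.12 and -0.099). Pairs on the same slide correlated at 0.084 to 0.23, so these values cannot tell whether letters mark litters. Without a label the letters were not used as pairs, and a block on them served as an alternative.

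The lists of genes, the rule for named genes, the tests and a set of other settings were fixed before the data were examined. The rule names Nkx6-1, the 12 largest rises and 12 largest falls among called genes with a symbol whose groups do not overlap, up to 4 called members of each list with the smallest p or, where none was called, the 2 with the largest difference, and 26 islet genes in any case where measured. Not all genes the rule takes in are given in the text. The 22 lists, with 362 tested genes, were islet transcription factors, glucose sensing and secretion, insulin synthesis and granule, alpha cell, delta cell, PP and epsilon cell, endocrine progenitor and dedifferentiation, genes repressed in islets, exocrine acinar, duct, endothelial, leukocyte and macrophage, mesenchyme and stellate, Schwann and glia, lymph node and fat, endoplasmic reticulum stress, proliferation, oxidative phosphorylation, glycolysis, cholesterol synthesis, immediate early and interferon response. Nkx6-1 was left out of them, and some genes stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry, and members were also counted adjusted over the list alone.

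The settings fixed at that stage were normexp background correction (offset 50) with and without quantile normalization, quantile normalization, scaling to the median, the deposited table of equalized values, no filter on dim probes, a filter on all 6 arrays, removal of outlier-flagged spots, slide or letter as a block, a variance trend with robust estimation, the mean or the lowest probe of a gene, an adjusted p under 0.1, a 1.5-fold minimum, and each array left out in turn. Alternatives chosen after seeing the data were quantile normalization with a slide block, cyclic loess, mutant arrays A and B left out, the mean of the acinar list as a covariate, and probes with a run of GAA repeats of 12 bases or more left out, with and without a slide block. The code was tested on simulated data for mutant against control, with 22775 genes and 50 changed genes per fold size. It recovered 2% of genes changed 1.5-fold, 42% at 2-fold, 64% at 4-fold and 78% at 8-fold, and it called 2 of 22575 unchanged genes. Each simulated gene took its spread as estimated from the real arrays. The adjusted threshold also depends on how many genes change, so the recovered shares do not carry over to the real data. For the gene lists, 1 simulated list shifted 1.5-fold passed and 0 of 200 others did. The simulated genes varied independently of each other and without a slide effect. In the real data the lists past camera had estimated correlations of 0.11 to 0.91. The simulation therefore does not show how often lists of correlated genes pass by chance.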

Results

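The arrays measured gene expression in islets isolated from the pancreas of 6-week-old male mice. Each of the 6 RNA samples pooled material from 2 pancreata of 1 genotype, and 3 samples were controls and 3 were mutants. The mice carried a floxed Nkx6-1 allele and Pdx1-CreERTM, a tamoxifen-activated recombinase expressed in the pancreas, and all had received 4 tamoxifen injections of 2 mg per 25 g body weight from the age of 4 weeks. Mutants had a null allele opposite the floxed one and controls a wild-type allele, so controls kept 1 copy outside the reach of the recombinase. Of 39429 probes per array, the share well above background was 73.4%, 75.6% and 76.3% in control arrays A, B and C, and 66.8%, 63.9% and 74.4% in mutant arrays A, B and C. The lowest background-corrected signals of mutant arrays A and B were 7.98 and 6.85, against 2.31 to 3.31 on the other 4 arrays, and the scanner software marked mutant A alone for evaluation. The number of called genes without both arrays is given in the closing section. Arrays of 1 group correlated across genes at 0.979 to 0.995 and arrays of different groups at 0.974 to 0.984, where genes are not independent replicates. Control A, mutant B and mutant C shared slide 1, and control B, control C and mutant A shared slide 2, so each slide held both groups. The number of arrays limits the precision of every value.

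The comparison of mutant with control islets asked which genes change with the loss of Nkx6-1, a transcription factor of beta cells. Mutants carried the null allele before tamoxifen too. Effects of that allele cannot be told apart here from those of the induced deletion. Nkx6-1 itself had a mean normalized log2 signal of 4.76 ± 0.10 (SD, n = 3) in controls and 4.28 ± 0.20 (SD, n = 3) in mutants. The difference of -0.48 (SE 0.14) put all 3 mutant arrays below all 3 control arrays but did not pass the threshold (limma, adjusted p = 0.131). With slide as a block it was -0.48 (adjusted p = 0.155), with -0.53 within slide 1 and -0.43 within slide 2. The array carries a single Nkx6-1 probe, at positions 102088319 to 102088378 of chromosome 5 (mm9). The labels do not state which part of the gene the floxed allele loses, so whether the probe lies in it is not known.

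Single genes of beta cell glucose uptake, granule docking and proinsulin folding fell in mutant islets, and the endocrine progenitor factor Neurog3 rose. Slc2a2, the GLUT2 glucose transporter, was 4.02-fold lower (log2 difference -2.01, SE 0.32, n = 3 per group), Sytl4 (granuphilin, a granule docking protein) 5.46-fold lower, with an SE of 0.14, and Ero1b, an oxidase of proinsulin folding, 2.87-fold lower, with an SE of 0.17. Neurog3 was 4.51-fold higher (log2 difference 2.17, SE 0.19). Cox6a2, a subunit of cytochrome c oxidase known from muscle, fell 53.5-fold, and Ptger3, a prostaglandin E receptor, rose 19.2-fold. The insulin genes did not pass, with Ins1 at 7.83 ± 0.24 (SD, n = 3) in controls and 8.09 ± 0.26 (SD, n = 3) in mutants.

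Of 22775 gene names tested, 576 passed the threshold, 320 higher and 256 lower in mutants. Without a filter on dim probes 413 of 31829 passed, 314 higher and 99 lower. At least 2-fold changes numbered 337, of which 212 were rises and 125 falls. In each of the 576 genes the 3 mutant arrays lay on 1 side of the 3 control arrays, which their selection by a small p favours. Of all genes tested, 26.3% had arrays that did not overlap, against 10% from chance for 3 against 3. The 10% holds for genes chosen without regard to group, while the filter admitted genes above background in 1 group alone. Genes also move together, so these shares decide nothing. With slide as a block 670 genes passed, 361 higher and 309 lower, and 437 genes passed both ways. In fits with 1 array fewer the count was 396 without control A, 13 without control B, 17 without control C, 22 without mutant B, 180 without mutant C and 305 without mutant A, and it was 139 with the mean acinar signal of each array as a covariate. With the replicate letter as a block limma called 0 genes, with 3163 at an unadjusted p under 0.05. Of the 39 genes that the naming rule takes in and that passed, 35 also passed with slide as a block, all but Mlph, Etv1, Oat and Ddit3, and 4 passed with each array left out in turn, namely Cybrd1, Rhox3a, Cox6a2 and Sytl4.

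**Figure D1:**
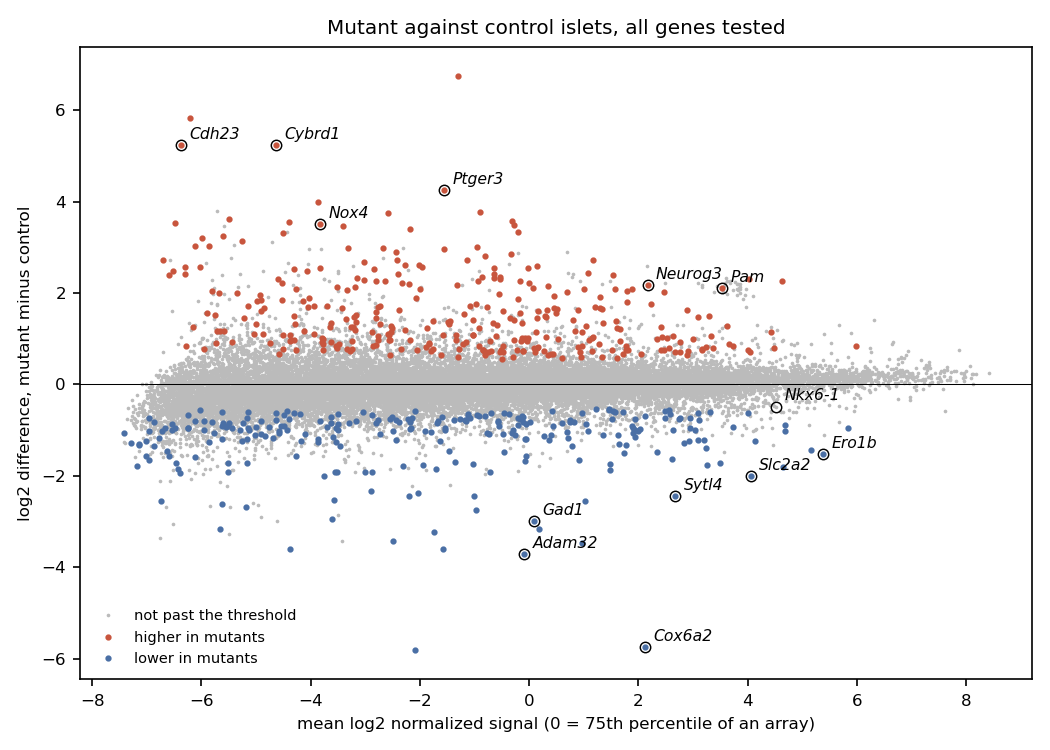
Mean normalized log2 signal over the 6 arrays (x axis) against the log2 difference, mutant minus control (y axis), for each of the 22775 gene names tested. Coloured points are the 576 genes past the adjusted threshold, 320 higher and 256 lower, and the labelled Ptger3 and Cox6a2 lie at 4.26 and -5.74.

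The 12 largest rises among genes with a symbol, of which 11 are given here, took in enzymes, receptors and a family of homeobox genes. Cybrd1, a ferric reductase, rose by 5.24 on the log2 scale (SE 0.30, adjusted p = 0.00601). Ptger3 rose by 4.26 (adjusted p = 0.00601), Nox4, an NADPH oxidase, rose 11.3-fold, Nt5e, the ectoenzyme CD73, 11.7-fold, and the secreted matricellular protein gene Ccn3 13.4-fold. The cadherin gene Cdh23 and the secreted protein gene C1ql3 were above background on no control array and were each at least 10.9-fold higher on the background-corrected signal, and Cybrd1 was above background on 1 control array. Dim genes rose less under normexp background correction, whose offset draws low signals together, with 2.93 for Cybrd1, 1.70 for Cdh23, 1.66 for C1ql3, 2.13 for Nt5e, 2.51 for Nox4, 2.96 for Ccn3 and 2.69 for Rhox3a, and all of these passed. The remaining 4 were the X-linked homeobox genes Rhox3a, Rhox3c, Rhox3f and Rhox3h, with differences of 3.99, 3.78, 3.57 and 3.49. These paralogs have related sequences, so their rises are not independent of each other.

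The 12 largest falls ranged from -5.74 to -2.56. Cox6a2 went from 4.99 ± 0.18 (SD, n = 3) to -0.75 ± 0.39 (SD, n = 3), with an adjusted p of 0.00137. Trpm5, a cation channel of the secretory response, fell 8.91-fold, Gad1, which makes GABA, 7.91-fold, and Angptl7, a secreted protein gene, 12.1-fold. Adam32 fell 13.2-fold, T2 9.42-fold, Cyp4f39 7.66-fold, Gp9 6.39-fold and Fam151a 5.88-fold. Dok7, above background on no mutant array, was at least 4.17-fold lower on the background-corrected signal. Insyn2a fell by 3.60 on the log2 scale, while its other probe read -0.70. Mlph fell by 2.62, and its adjusted p was 0.0599 with slide as a block. Gp9 and Mlph were above background on 1 mutant array each. Under normexp the differences were -1.04 for Dok7, -0.95 for Gp9, -1.94 for Cyp4f39, -2.13 for Insyn2a and -0.84 for Mlph, which did not pass there (adjusted p = 0.0716).

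The list of glucose sensing and secretion genes fell as a group, with a median log2 difference of -0.14 over 28 members (camera, adjusted p = 0.00501). Its adjusted p was 0.890 with an estimated correlation. With slide as a block the adjusted p was 0.0200, and the medians were -0.093 and -0.17 within slides 1 and 2. Of the members, 5 fell and 0 rose, and adjusted over the list alone 9 fell and 1 rose. Slc2a2 fell by 2.01 (adjusted p = 0.0415), Trpm5 fell by 3.16, Ucn3, a peptide of mature beta cells, fell by 1.24 (adjusted p = 0.0236) and Pcx, pyruvate carboxylase, fell by 1.00. The remaining fall, Ffar1, a fatty acid receptor named after its value was seen, fell by 0.99. G6pc2 at -0.81 (adjusted p = 0.130) and Glp1r at -0.89 (0.191) did not pass, though Glp1r passed without control A (0.0326). Without mutant C the adjusted p of the list was 0.0841.

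Among 21 genes of insulin synthesis and the granule, 3 fell and 1 rose, and adjusted over the list alone 3 fell and 5 rose. Sytl4 fell by 2.45 (adjusted p = 0.00601), Ero1b fell by 1.52 (adjusted p = 0.0210) and Slc30a8, the granule zinc transporter, fell by 0.96 (adjusted p = 0.0282), while Pam, which amidates peptides, rose by 2.11 (adjusted p = 0.0277). The list did not pass, with a median of 0.25 and an adjusted p of 0.136, but it passed upward without control A (0.0402) and without mutant A (0.0165). Ins1 (0.26), Ins2 (0.25) and Iapp (0.26) did not pass, with adjusted p values of 0.481, 0.702 and 0.673, and their signs and the list median turned negative under quantile normalization. Ins1 had saturated pixels on 5 arrays, which limits how far its signal can follow its level.

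Of 17 islet transcription factor genes, Rfx6 rose by 0.75 (adjusted p = 0.0335) and the others did not pass. Adjusted over the list alone, 1 rose and 1 fell. Mafa, an activator of insulin genes, was at -0.77 (adjusted p = 0.0594), Pdx1 at -0.39 (0.248) and Neurod1 at -0.42 (0.132). Mafa passed with a filter on all 6 arrays and with a variance trend and robust estimation. Nkx2-2 was at -0.22, Pax6 at 0.27 and Isl1 at 0.24, with adjusted p values of 0.279, 0.248 and 0.240. The list had a median of -0.070 and an adjusted p of 0.805.

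**Figure D2:**
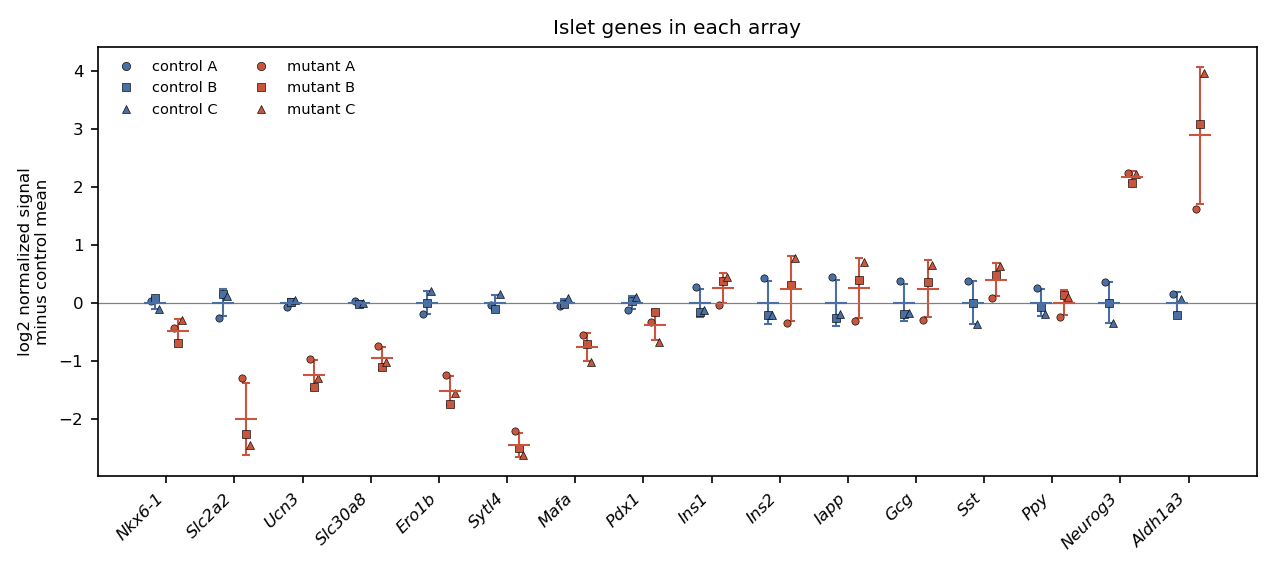
Normalized log2 signal minus the control mean (y axis) for 16 islet genes (x axis) in the 3 control and 3 mutant arrays. Points are arrays, with a marker for each replicate letter, dashes are group means and bars SD (n = 3), and Slc2a2 and Neurog3 lie at means of -2.01 and 2.17 in mutants, while the positive means of Ins1, Ins2, Iapp and Gcg turn negative under quantile normalization.

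The alpha cell list rose as a group, with a median of 0.49 over 11 members (camera, adjusted p = 0.00501). Its adjusted p was 0.890 with an estimated correlation. Blocking by slide gave an adjusted p of 0.0200, and the medians within slides 1 and 2 were 0.36 and 0.47. Etv1 rose by 1.29 (adjusted p = 0.0435, 0.0654 with slide as a block), and adjusted over the list alone 5 rose and 1 fell. Gcg, the glucagon gene, was at 0.24 (adjusted p = 0.674) and negative under quantile normalization. Without a filter on dim probes the adjusted p of the list was 0.136.

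The list of endocrine progenitor and dedifferentiation genes rose too, with a median of 0.50 over 13 members (camera, adjusted p = 0.0106). Its adjusted p was 0.890 with an estimated correlation. Its adjusted p with slide as a block was 0.0443, and the medians within slides 1 and 2 were 0.44 and 0.60. Neurog3 rose by 2.17 (SE 0.19, adjusted p = 0.0139) and Serpina7, which encodes thyroxine-binding globulin, by 2.32 (adjusted p = 0.0372). Adjusted over the list alone 7 members rose and 1 fell. Aldh1a3, a retinaldehyde dehydrogenase, was at 2.89 and did not pass (adjusted p = 0.0637). Among fits with more than 1 sample per group, it passed without mutant A and with the acinar covariate. It also passed under normexp with quantile normalization and with a variance trend and robust estimation. Without a filter on dim probes the adjusted p of the list was 0.241.

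Of 10 delta cell genes, 1 rose and 0 fell, and adjusted over the list alone 2 rose and 0 fell. Sst was at 0.40 (adjusted p = 0.398) and Hhex, a delta cell factor, at 0.74 (0.321). The delta cell list had a median of 0.32 and an adjusted p of 0.0798, which was 0.0478 without control A and 0.0345 without mutant arrays A and B. Ppy had a mean of 8.13 in both groups, but its difference ran from -0.39 to 0.11 over the alternatives, fits with 1 array left out aside. Pyy was at 0.037 (0.895) and negative under quantile normalization, and Ghrl was at -0.55 (0.757). The PP and epsilon cell list of those 3 genes had a mean of -0.17, upward in camera, with an adjusted p of 0.996. Gcg, Sst and Ppy had saturated pixels on 4, 5 and 3 arrays.

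The exocrine acinar list, digestive enzymes of the surrounding tissue, had no member past the threshold and rose as a group of 28 genes (median 0.58, camera, adjusted p = 0.0106). Its adjusted p was 0.890 with an estimated correlation. Within slide 1 the median was 1.64 and within slide 2 it was -1.04, and with slide as a block the adjusted p was 0.238. The mean of the list relative to the control mean was -0.81, 0.93 and 1.88 in mutant arrays A, B and C and -0.25, -0.079 and 0.33 in control arrays A, B and C. Over the same arrays the mean of the glucose sensing list was -0.31, -0.47 and -0.58 in mutants, of the alpha cell list 0.33, 0.62 and 0.67, and of the progenitor list 0.53, 0.83 and 1.06. Ctrc, a chymotrypsin, was at 1.40 (0.339) and the phospholipase gene Pla2g1b at 1.29 (0.559). Without mutant C the adjusted p of the list was 0.578, without mutant B it was 0.106, and under quantile normalization it was 0.155. The call was also lost with the deposited equalized values (0.0681), cyclic loess (0.0647) and no filter on dim probes (0.186).

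The mesenchyme and stellate cell list rose (median 0.38 over 15 members, adjusted p = 0.0368) with no member past the threshold. Its adjusted p was 0.890 with an estimated correlation. A slide block gave an adjusted p of 0.241, and the medians within slides 1 and 2 were -0.34 and 0.89. The collagen gene Col5a1 was at 0.90 (0.285) and Postn, periostin, at 0.78 (0.417). The list of genes normally repressed in islets rose as well (median 0.19 over 17 members, adjusted p = 0.0363). Its adjusted p was 0.890 with an estimated correlation. With slide as a block the adjusted p was 0.204, and the medians within slides 1 and 2 were 0.0060 and 0.48. Its called member was Oat, ornithine aminotransferase, which rose by 1.05 (adjusted p = 0.0433, 0.0641 with slide as a block), and adjusted over the list alone 2 rose and 0 fell. Both lists lost their call without control C, at adjusted p values of 0.414 and 0.191, and without mutant A, at 0.120 and 0.0688. Without a filter on dim probes both had an adjusted p of 0.241, and with a filter on all 6 arrays 0.0706 and 0.0649. The mesenchyme list also lost its call under normexp (0.0806) and cyclic loess (0.0647), and the repressed list with the mean (0.0653) or the lowest (0.0888) of a gene's probes. The mesenchyme list also lost it without control B (0.128) or mutant B (0.108), and the repressed list without mutant C (0.255).

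The lists of other cell types did not pass. Adjusted over the list alone, 2 duct genes were higher and 1 lower, and 0 genes of the acinar, mesenchyme, endothelial, leukocyte, Schwann, lymph node, and PP and epsilon cell lists passed. The duct list had a median of -0.069 and a mean of 0.19, upward in camera (adjusted p = 0.805), with Cftr at 3.12 (0.0831, 0.0157 with slide as a block) from a probe with a GAA repeat run of 11 bases, and Krt19 at -1.10 (0.291). The endothelial list had a median of 0.15 (0.134), and it passed without control A (0.00102), with Cldn5 at -0.42 (0.677) and Egfl7 at 0.36 (0.323). The leukocyte and macrophage list had a median of -0.15 (0.356). Its member Cd3e was at -0.55 (0.0957, 0.0467 under normexp with quantile normalization) and Itgam at -0.49 (0.249). The Schwann cell and glia list had a median of 0.11 (0.356), with S100b at 0.48 (0.366). The lymph node and fat list had a median of -0.19 (0.510), with Ccl21a at -2.87 (0.314) and Lep at -0.55 (0.390). The values in brackets are adjusted p values.

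Of the lists of cell states, the endoplasmic reticulum stress list had a median of 0.13 (0.510) and 1 called member, Ddit3, the stress factor CHOP, which fell by 0.64 (0.0478, 0.0616 with slide as a block). Adjusted over the list alone 2 members fell and 0 rose. The proliferation list had a median of -0.17 (0.274) and 1 called member, Ccnd2, cyclin D2, which fell by 1.03 (0.0200); adjusted over the list alone 1 fell. Without control B that list passed, at a median of -0.39. The oxidative phosphorylation list had a median of 0.062 (0.217), negative under quantile normalization and past the threshold, upward, without control A (0.0348) or mutant A (0.0166), with Ndufa1 at 0.54 (0.245) and Ndufa4 at 0.34 (0.273). The glycolysis list had a median of -0.053 and a mean of 0.040, upward in camera (0.805), with Ldha at 0.41 (0.435) and Eno1 at 0.41 (0.491). The cholesterol synthesis list had a median of -0.039 and a mean of -0.028, upward in camera (0.996), with Idi1 at 0.32 (0.390) and Srebf2 at -0.29 (0.546). The immediate early list had a median of -0.24 (0.356, 0.00730 without mutant arrays A and B), with 1 fall adjusted over the list alone, Fosb at -0.79 (0.0722, 0.0389 with slide as a block) and Nr4a1 at 0.65 (0.463). The interferon response list had a median of 0.068 (0.629, 0.0299 with the acinar covariate). Its member Mx1 was at -1.02 (0.489, 0.0444 without mutant A) and Isg15 at 0.48 (0.426). The values in brackets are again adjusted p values, and 0 genes of the oxidative phosphorylation, glycolysis, cholesterol and interferon lists passed when adjusted over the list alone.

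In all, 6 of the 22 lists passed camera with its preset correlation, 3 with slide as a block, 0 with an estimated correlation and 0 in fry's test of 1 direction, where the lowest adjusted p was 0.236, for the glucose sensing and the progenitor lists. Fry's test of change in either direction, which does not compare a list with other genes, passed for 11 lists.

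**Figure D3:**
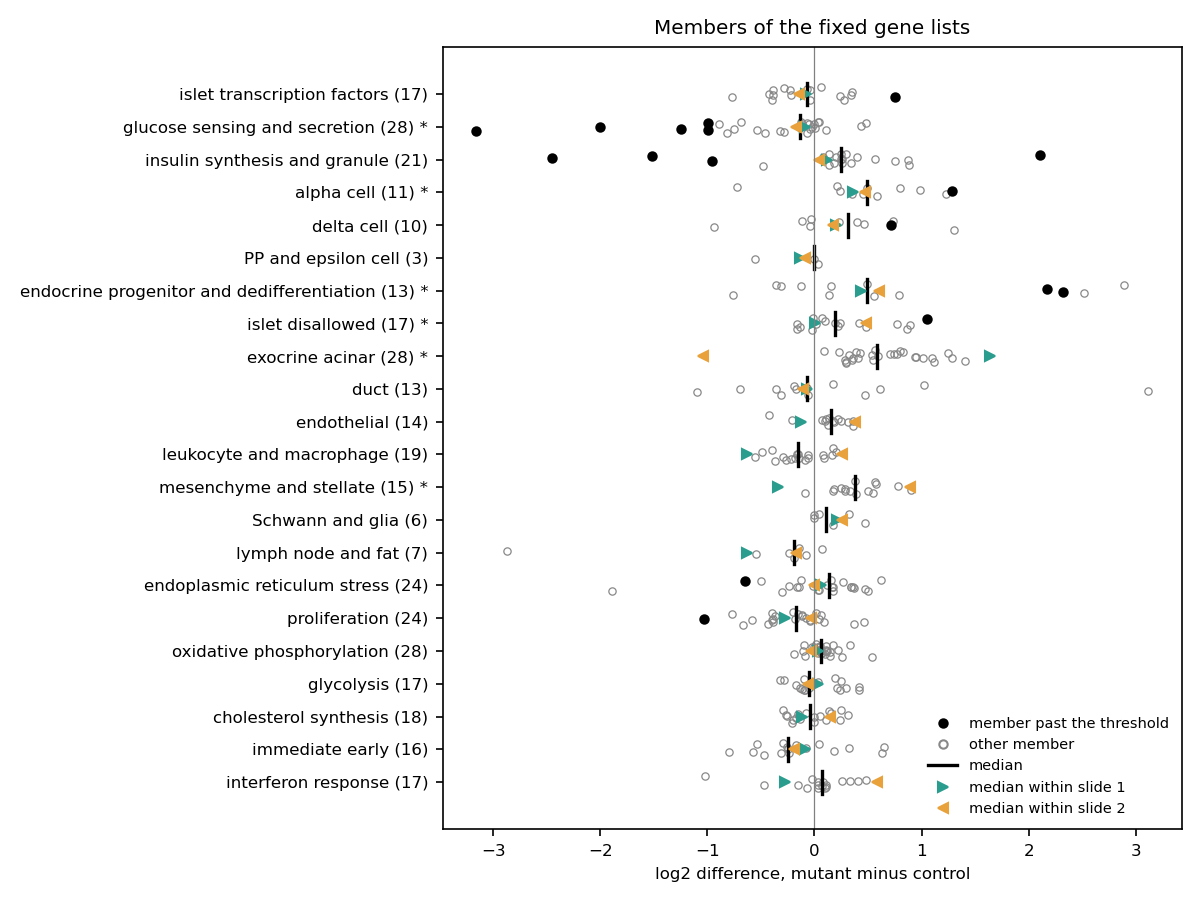
Log2 difference, mutant minus control, of the tested members (points) of each of the 22 gene lists. Filled points passed the threshold, bars are list medians, triangles are medians within each slide and asterisks stand by the 6 lists past camera; the acinar medians within the slides are 1.64 and -1.04.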

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

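The slide block with quantile normalization, cyclic loess, the fit without mutant arrays A and B, the acinar covariate and the removal of probes with GAA runs were chosen after the data were seen, and the other alternatives were planned. The count of called genes, 576, lay between 413 and 785 under the planned scalings, background corrections, filters, variance models, probe choices, outlier removal, the slide block and the 1.5-fold minimum, and between 522 and 636 with cyclic loess, quantile normalization with a slide block, or without the GAA probes. It was 0 with the replicate letter as a block (limma, 3163 at an unadjusted p under 0.05), where no label says that letters pair the samples and the cause was not tested, and 1514 at an adjusted p under 0.1, a looser threshold. It was 139 with the acinar covariate, 121 of them shared with the 576, and 150 without mutant arrays A and B, 28 shared, where the lone mutant sample is assumed to vary like the controls. Leaving out each array gave 13 to 396 genes, with fewer samples in each fit: 396 without control A, 13 without control B, 17 without control C, 305 without mutant A, 22 without mutant B and 180 without mutant C. Why single arrays weigh so unequally was not tested. Nkx6-1 lay between -0.60 and -0.31 (adjusted p 0.0845 to 0.429) over the alternatives and between -0.57 and -0.37 with 1 array left out, and passed under none. The number of lists past the threshold, 6, was 1 without a filter on dim probes, 3 with a slide block, 3 with quantile normalization and a slide block, 3 with the GAA probes out and a slide block, 0 with an estimated correlation, 0 in fry's test of 1 direction, and 3 to 10 with 1 array left out; it was 4 to 7 otherwise, and the cause was not tested. The 39 genes past the threshold that the naming rule takes in kept their direction under all alternatives that measured them. Of the 39, 0 stayed past it with the letter block, 27 without a filter on dim probes, 16 with the acinar covariate, 9 without mutant arrays A and B, 24, 4 and 7 without control A, B and C, 29, 6 and 16 without mutant A, B and C, and 35 or more under each of the other settings that measured all 39, while 32 of the 32 measured did so with a filter on all 6 arrays. Among all 576 genes, 9 had the opposite sign with the lowest-signal probe, 3 under normexp, and 1 each without control B, control C or mutant C, without mutant arrays A and B, and, of 566 measured, without the GAA probes with and without a slide block. Among the genes and lists named in the text, a change of sign was seen for results that had not passed, and for the acinar list under the acinar covariate (-0.055), which removes that signal by construction. For genes these are log2 differences and for lists medians. Under normexp with quantile normalization they were -0.018 for the insulin list, -0.0069 for oxidative phosphorylation, -0.22 for Pyy, -0.018 for Ins1, -0.18 for Ins2, -0.067 for Iapp and -0.17 for Gcg. In the same order quantile normalization gave -0.044, -0.017, -0.19, -0.14, -0.13, -0.044 and -0.10, and quantile normalization with a slide block gave -0.025, -0.023, -0.11, -0.099, -0.18, -0.12 and -0.14, with -0.012 for endoplasmic reticulum stress and 0.051 for cholesterol synthesis. The deposited equalized values gave -0.22 for Pyy, -0.023 for Ins1, -0.057 for Ins2, -0.078 for Iapp and -0.038 for Gcg. Normexp alone gave -0.014 for Pyy and 0.054 for Lep. The slide block, with or without the GAA probes, gave 0.051 for cholesterol synthesis, -0.026 for Pyy and -0.0089 for Ins2. Cholesterol synthesis was 0.012 with the mean of probes, 0.0097 with cyclic loess and 0.056 with the acinar covariate, and Pyy -0.10 and -0.024 in the last pair. Without mutant arrays A and B the duct list was 0.17, lymph node and fat 0.095, interferon response -0.095, Lep 0.061 and Nr4a1 -0.36. With 1 array left out, the ranges that crossed 0 were -0.30 to 0.099 for the leukocyte list, -0.52 to 0.16 for the lymph node and fat list, -0.079 to 0.015 for glycolysis, -0.11 to 0.23 for interferon response, -0.20 to 0.054 for cholesterol synthesis, -0.82 to 0.18 for Cldn5, -1.65 to 0.045 for Ghrl, -0.041 to 0.12 for Pyy and -0.019 to 0.54 for Ins2, and, around values of 0, -0.070 to 0.12 for the PP and epsilon cell list and -0.095 to 0.13 for Ppy. The cause of these changes of sign was not tested. Signal over background limited detection, since 10 genes called higher were above background on no control array and 29 called lower on no mutant array.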

Other observations

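The genes in the first paragraphs were chosen after their values were seen, and so were the tests of the slide, of alpha cell genes against other cell types, of the acinar list within slides, of ChREBP targets and of the GAA repeat, while the tests of splits, haplotype and other beta cell genes were written before their results were seen.

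Some genes outside the fixed lists rose in mutant islets, and no group of them was tested. Txnip, a thioredoxin-binding protein gene that responds to glucose, rose by 2.31 on the log2 scale (SE 0.14, adjusted p = 0.00601), and its relative Arrdc4 by 2.34 (adjusted p = 0.0210). Pfkfb3, which makes an activator of glycolysis, rose by 2.85 (0.0151), the glycerol kinase gene Gk by 2.53 (0.00338), the fatty acid transporter gene Cd36 by 2.91 (0.0151) and the fatty acid binding protein gene Fabp5 by 2.05 (0.0267). The peptide gene Cartpt rose by 2.25 (0.0181), the secreted peroxidase gene Gpx3 by 2.26 (0.00918), the kinase gene Dclk1 by 2.73 (0.00338) and the water channel gene Aqp4 by 3.34 (0.0151). The bracketed values are adjusted p values. For each gene all 3 mutant arrays lay above all 3 control arrays, which holds for every called rise and adds no support.

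Other single genes fell. Atf5, a stress-related transcription factor gene, fell by 1.82 (adjusted p = 0.0151), Prss53, a serine protease gene, fell by 1.73 (0.0125), Maob, monoamine oxidase B, fell by 1.63 (0.00601) and Papss2, which makes the sulfate donor, fell by 1.42 (0.00757). Atp2a2, the calcium pump SERCA2, fell by 1.21 (0.0212), Hadh, a fatty acid oxidation enzyme gene, fell by 0.88 (0.0354), the gap junction gene Gjd2 fell by 0.75 (0.0267) and the corepressor gene Tle3 fell by 1.16 (0.0151). The unnamed transcript 4931431B13Rik fell by 5.82 (0.00137), and its probe starts at position 135345617 of chromosome 7 (mm9), beside that of Cox6a2 at 135349160.

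Chance, slide and strain were weighed as sources of the 576 calls. The 6 arrays can be split 10 ways into 3 and 3, too few for a share under 0.05: 1 split, the real one, gave as many genes, and the highest of the others gave 33, while for lists 6 splits gave at least the 6 of the real one and the highest other gave 12. That highest other split follows the slides. At an unadjusted p under 0.05 (limma) it gave 4649 genes and the real split 4600, where the slides in part follow the groups. The tested genes had been filtered by the real groups, which favours the real split. A real group difference also widens the spread within the other splits and lowers their counts. These gene counts therefore decide nothing about chance. With slide as a block 437 of the 576 genes stayed past the threshold, which their choice in the first fit favours, and 3 lists passed. In all, 670 genes passed with that block, chosen without the first fit, and they argue against the slides as the whole source of the gene count. A linked strain haplotype around Nkx6-1, carried on the null allele in mutants alone, would put many called genes near it, but 2.61% of called genes lay within 20 Mb of its probe against 1.75% of tested genes (odds ratio 1.52, two-sided Fisher's exact p = 0.143), which argues against it as the whole source and leaves the 15 genes in that window, and variants elsewhere, open. The loss of Nkx6-1 that the design names, by the null allele, the induced deletion or both, remains open as a biological source.

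The fall of the glucose sensing list did not pass camera with an estimated correlation (adjusted p = 0.890) or fry's test of 1 direction (adjusted p = 0.236). Other splits of the arrays gave as many lists as the real one, so chance is not excluded as its source. If the fall is real, it could come from a lower share of beta cells or from lower expression within them. Other beta cell genes did not decide, with a median of -0.33 over Prlr (-0.94), Ppp1r1a (-1.33), Nnat (-0.33), Npy (-0.32), Mnx1 (0.64) and Dlk1 (1.44), which went both ways. Ins1 (0.26), Ins2 (0.25) and Iapp (0.26) did not fall, but their signs turned negative under quantile normalization. Ins1 also had saturated pixels on 5 arrays, while Ins2 and Iapp had them on 0. Because of the change of sign these genes did not decide either. A lower beta cell share would raise the markers of other cells alike, and the alpha cell list rose by 0.27 (SE over arrays 0.165, 108 genes) more than all other lists of such cells pooled, a difference too close to its error to decide. Against the endothelial, leukocyte, duct and glia lists pooled it was 0.49 (SE 0.147). The mesenchyme, delta and acinar lists had means of 0.40, 0.27 and 0.66, against 0.54 for the alpha cell list. Taken singly, the difference was 0.13 (SE 0.29) from the mesenchyme list and -0.13 (SE 0.75) from the acinar list. It was 0.27 (SE 0.13) from the delta list and 0.71 (SE 0.41) from the PP and epsilon cell list. It was 0.41 (SE 0.15) from the endothelial, 0.68 (SE 0.26) from the leukocyte, 0.35 (SE 0.21) from the duct and 0.37 (SE 0.24) from the glia list. The difference thus varied with the list it was set against. Both explanations stay open, since the samples hold whole islets, and so does chance.

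The acinar list may reflect exocrine tissue carried over in different amounts from pool to pool. Its median was -1.04 within slide 2 and 1.64 within slide 1, and its members moved together (estimated correlation 0.911), as carry-over would give. Signals of its enzyme genes, which cannot be ranked between probes and decide nothing here, were for example Try5 at 7.85 in controls and 8.13 in mutants, Ctrb1 at 7.63 and 7.92 and Amy2a5 at 7.65 and 7.74. The labels name no step that removes acinar cells beyond islet isolation, no gene of the list stands in another list, and how many of them islet cells express was not analysed here. An effect of genotype on acinar genes was not tested apart from carry-over, and the group median of 0.58 fell to 0.0064 without mutant C.

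The rise of Txnip, Arrdc4, Rgs16 and Acacb prompted the hypothesis that targets of ChREBP, a glucose-responsive transcription factor, rose more widely. Acacb lies in the window around Nkx6-1 for which a linked strain haplotype was left open. In a list of 14 other targets, written after it was known that none of them was called, the median was -0.22. A list that leaves out the called targets decides nothing, so the hypothesis stays open.

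A set of unrelated gene names, among them Dcc, Gcm1 and Gab3, shared 1 profile over the arrays, which may come from a GAA repeat in their probes. Of 45 tested probes with a GAA run of 18 bases or more, 88.9% lay above 1 in log2 within both slides, against 0 of 35 probes with as long a run of another 3-base repeat and 1.23% of all other probes. Their mean was 3.64, 1.62 and 1.91 in control arrays A, B and C and 3.28, 4.92 and 4.95 in mutant arrays A, B and C. Of 67 genes represented by a probe with a run of at least 12 bases, 12 were called, all higher, among them Notch1 at 2.21, and 55 were called with a slide block. Cftr, with a run of 11 bases, was kept when such probes were left out. Without such probes 560 genes were called, and 522 with a slide block. The origin of the repeat signal was not tested.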
